A study of Streptomyces lividans with 12 samples.

How the data were processed

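The data were 12 RNA-seq libraries of Streptomyces lividans, 3 from the wild type and 3 from each of the mutants H_D1, H_D34 and A_D28. The groups and replicate numbers were taken from the labels. Per the submitters' processing notes, reads had been trimmed with fastp, aligned with Bowtie2 and counted with RSEM. The expected counts (estimated reads per gene) were used as deposited, with 1 column per library and whole numbers in every cell. TPM (length-scaled transcript levels) were deposited beside them and had been scaled by the authors within each library, with column sums of 999999.66 to 1000000.8. Versions of these tools, the genome build, the annotation and the chromosome coordinates were not given in the sources used here. The reads themselves were not analysed here. Of the 7485 genes in the table, 3252 had a symbol and 3708 were annotated as hypothetical protein. Locus numbers that the table skips were not analysed here. Identical counts in all 12 libraries were found for 34 gene copies in 13 groups.

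Differential expression was tested on the deposited expected counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 7089 genes, library sizes were scaled by TMM factors, and 1 quasi-likelihood model (glmQLFit and glmQLFTest) with the 4 strains was fitted to all 12 libraries. P-values were adjusted by the Benjamini-Hochberg method over the tested genes within each comparison, and an adjusted p under 0.05 was a call. Each mutant was compared with the wild type and with each other mutant, and a joint test asked whether any strain differed. Fold changes are log2 values relative to the TMM scale. The mean TMM factors were 1.11 for the wild type, 0.712 for H_D1, 1.24 for H_D34 and 1.02 for A_D28, so that scaling by library size alone moves all genes of a comparison together. Where a group had 0 counts, the fold was given as a bound against 3 counts over the group, and with 1 to 3 counts as a ratio with its 95% counting interval. A list's median was also taken with such genes at their bound.

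Gene lists were fixed by patterns in product names and symbols before the data were examined, as were the model, the gene-naming rule and the other settings listed at the end. Of 42 lists, 36 had 5 or more tested genes and were tested, 4 had 1 to 4 tested genes and 2 matched no gene. The set test was camera in limma 3.58.1 on voom values with a preset correlation of 0.01 between genes, adjusted over the lists of a comparison by Benjamini-Hochberg. It was repeated with the correlation estimated from the data, and calls adjusted over the list alone were counted. The pattern for the regulator OxyR in the oxidative stress list also matched product names that contain deoxyribo, so a list without these was added after the data were seen. The region from redW to pigC was also singled out then, so it is described by counts and medians without its set test.

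Neighbourhood was read from the locus numbers. A run without reads was 5 or more neighbouring genes with 3 or fewer counts in every library of a mutant and a mean of 10 or more counts in the wild type. A terminal segment extended from the first to the last such run at an end. Windows of 20 neighbouring genes were compared with 10000 random sets of 20 genes by their median fold change. Windows left out the genes in runs of the mutant they describe. Leaving out the 947 genes in the runs of any mutant was fixed beforehand for the gene counts and added later for the lists.

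Genes were named by a rule. For each mutant these were the 6 highest and 6 lowest fold changes among called genes with an annotated product, a mean count of 100 or more in the higher group and no overlap between the libraries of the groups. The rule also named 2 members of up to 6 called lists, 6 genes each way over all 3 mutants, and 4 genes each way for each pair of mutants. Because the lowest genes by this rule had no reads in the mutant, the same rule was applied outside the runs after the data were seen. Genes named beyond the rule are marked as such in the text.

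At these depths 3 counts in a single library stood for 0.202 to 0.517 CPM. Between libraries of a strain, the chi-square per degree of freedom of genes with 10 or more counts was 2.55 to 28.7, where counting noise alone gives 1. The 10 genes with the most counts took 16.2% of the wild type counts, 21.4% in H_D1, 15.6% in H_D34 and 20.9% in A_D28. The methods were tested on simulated data drawn from the wild type means and the fitted dispersion of each gene, with 200 genes changed in each comparison. edgeR called in the right direction 60 to 82% of genes changed 1.5-fold, 82 to 98% of those changed 2-fold, 98 to 100% at 4-fold and 92 to 100% at 8-fold. Between 4 and 12 of the 6997 to 7008 genes tested were called without a change. A run of 40 absent genes was found whole, and raised ribosomal proteins were the 1 list called. With 20 neighbours raised 2-fold and the ribosomal proteins 1.5-fold in the same simulated mutant, 3 windows were called. Windows do not overlap, so not all of them can lie over the raised neighbours. Where no gene had been changed, 0 windows were called.

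Other settings were also run: DESeq2 1.42.0 size factors, upper-quartile factors or library size alone in edgeR, and no count filter or at least 10 CPM in 3 libraries. Other tests were the DESeq2 Wald test, limma-voom, limma-trend on log2(TPM + 1) and log2(TPM + 0.1). The samples were varied by fitting the compared groups alone, with a replicate block, and without each library in turn. The genes were varied by leaving out ribosomal RNA and the 10 highest genes, or the genes in runs. For lists they were the estimated correlation, fry (directional and mixed) and matched members alone. For runs they were a limit of 10 counts, a length of 10 genes and windows of 50. The 10 splits of the 6 libraries of each comparison and 100 regroupings of the 12 libraries were run through the same tests. Overlap between mutants was set against 20 simulated draws with unchanged groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.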

Results

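RNA-seq libraries had been made from 4 strains of Streptomyces lividans, a filamentous soil bacterium with a linear chromosome. The strains were the wild type and the mutants H_D1, H_D34 and A_D28, which came from spores exposed to a high-energy pulsed electron beam. Each strain had 3 libraries. Total counts ran from 10476315 to 13560562 in the wild type, from 8008471 to 9379863 in H_D1, from 8148858 to 10350888 in H_D34 and from 8087747 to 10487765 in A_D28. The count table held 7485 genes, of which 7089 passed the filter on low counts. Log2 counts correlated at 0.995 or more (Pearson's r across genes, which are not independent) between libraries of the same strain. The mean r was 0.78 to 0.816 between the wild type and the mutants, 0.899 between H_D1 and either other mutant, and 0.973 between H_D34 and A_D28. The labels do not say that the 3 libraries of a strain came from separate cultures, so p-values measure only the spread between these libraries, which could be technical. Each mutant was compared with its unirradiated parent, and then with the other mutants, to find which transcripts distinguish it. Genes carry the locus numbers of the deposited table, whose order was used to describe neighbours; chromosome coordinates and the genome build were not given in the sources used here. CPM values below are means ± SD (n = 3 libraries), and SE is the standard error of a log2 fold change.

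H_D1 had no or nearly no reads from long stretches at both ends of the locus order. Between ctg_00025 and ctg_00257 at the left end, 198 of the 201 loci expressed in the wild type had 3 or fewer counts in every H_D1 library, and between ctg_06846 and ctg_07624 at the right end 687 of 694 did. In the wild type these segments gave 2.62% and 4.17% of all counts. The most abundant annotated transcript among them was gap2_3, a glyceraldehyde-3-phosphate dehydrogenase of central carbon metabolism, with 3343 ± 30.5 CPM in the wild type and 0 counts in H_D1, at least 20900-fold lower against a floor of 3 counts over the group. Other transcripts with 0 counts in H_D1 were narG_1, the alpha subunit of nitrate reductase (at least 18000-fold lower), ppdK_1, a pyruvate phosphate dikinase (at least 9050-fold), ppiA, a peptidyl-prolyl isomerase (at least 7200-fold), and the alcohol dehydrogenases ctg_00143 (at least 6980-fold) and adh (at least 6230-fold). The universal stress protein gene ctg_00144 had 1 count in H_D1 against 69714 in the wild type, a ratio of 32500 (95% counting interval 5820 to 1280000). At the depth of the H_D1 libraries the wild type levels would have given a median of 212 counts per absent locus over the group. Of the 3 and 7 expressed loci that kept reads in these segments, 2 and 5 were transposases or identical copies, which can share reads with loci elsewhere.

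**Figure D1:**
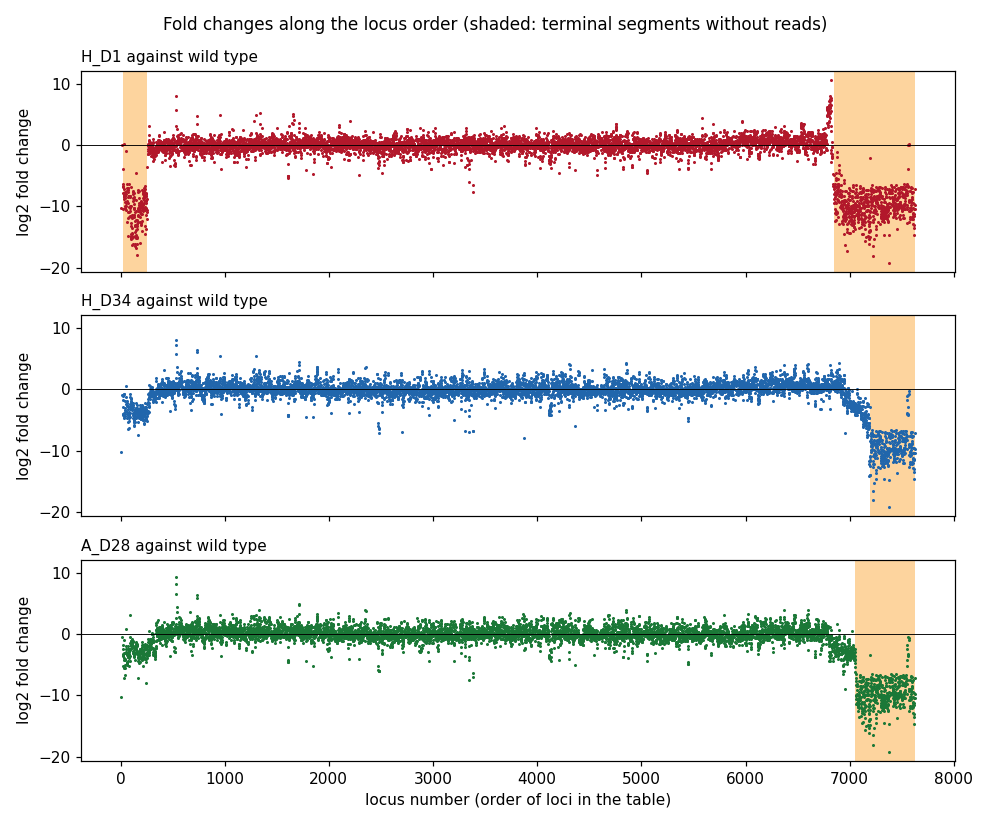
Log2 fold change of each tested gene against the wild type (vertical axis) in locus order (horizontal axis, locus number), for H_D1, H_D34 and A_D28, with the terminal segments without reads shaded. Genes in runs without reads lie at both ends in H_D1 and at the right end in H_D34 and A_D28, and the lowered ends of H_D34 (medians -3.58 and -3.20) and A_D28 (medians -2.71 and -2.76) reach further inwards.

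On the inner side of the right-hand segment, H_D1 had a block of neighbouring genes at very high levels. All 42 tested genes from ctg_06780 to tgnD_2 (ctg_06822) rose, by a median log2 fold change of 5.83 (range 2.26 to 10.62). The bounds of the block were drawn from these same fold changes, so the rise of every member is not a separate result. Between the block and the segment without reads lay 23 loci. The block took 2.83% ± 0.22 of the H_D1 counts and 0.0723% ± 0.00134 of the wild type counts (SD, n = 3). The 6 annotated genes with the highest fold changes in H_D1 all lay in it. They were rutD_5, a putative aminoacrylate hydrolase (2.36 ± 0.255 to 3711 ± 295 CPM, log2 10.62, SE 0.14, adjusted p = 1.03e-22), the flavohemoprotein hmp_4 (7.70), the regulator ctg_06808 (7.58), the putative cardiolipin synthase ywiE (7.26), yajO_9 (7.12) and the response regulator degU_11 (6.66). In H_D34 and A_D28 the median fold change of the block was 0.40 and -0.58. The block, the lowered ends and the ssrA share described below were singled out after the values were seen.

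**Figure D2:**
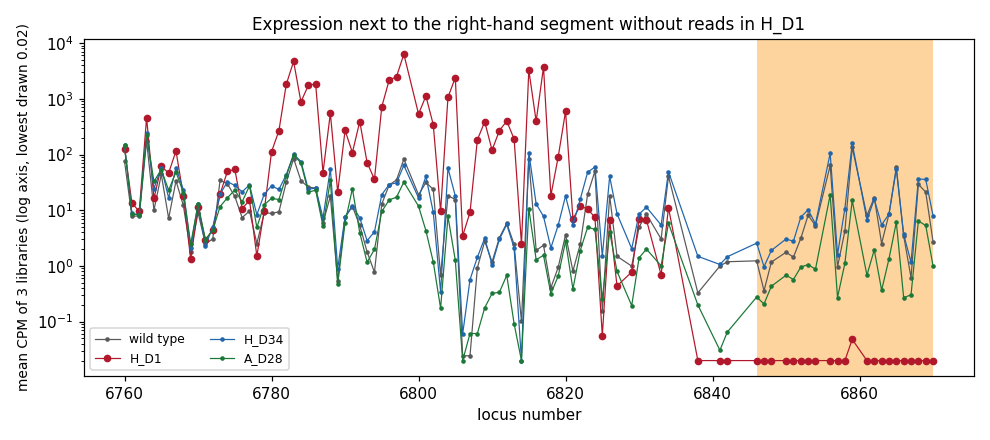
Mean CPM of 3 libraries (log axis, lowest value drawn 0.02) of the wild type and the 3 mutants at the tested loci around the right-hand edge of H_D1, in locus order, with the segment without reads shaded. The block from ctg_06780 to ctg_06822 stands above the wild type by a median log2 fold change of 5.83, and from ctg_06846 on the H_D1 values drop to the floor.

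Over all 7089 tested genes, 2557 were higher and 2778 lower in H_D1 than in the wild type (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 75.3% of the genes, and 941 and 1590 of them differed by 2-fold or more. Outside the runs of absent genes, 2557 were higher and 1932 lower. The lowest annotated genes outside the runs were sigE_2, the sigma factor of the cell envelope stress response (584.7 ± 19.7 to 9.13 ± 0.481 CPM, 63.9-fold lower, adjusted p = 1.44e-22), the serine protease inhibitor ctg_01608 (-5.03), IMPDH_3 (-4.63), tal_2 (-4.57), the glycosyltransferase mshA_6 (-4.20) and chpE (-4.10). chpE encodes a chaplin, a protein of the aerial hyphal surface. IMPDH_3 itself lay between loci without reads. With scaling by library size alone the median of all genes shifted by -0.64 log2 in H_D1, 0.16 in H_D34 and -0.12 in A_D28, and in H_D1 1115 genes were then higher and 4575 lower, 19.6% higher against 47.9% with TMM factors.

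Genes of translation and ATP synthesis were higher in H_D1, relative to the median gene. Of 51 ribosomal protein genes, 45 rose and 0 fell (median log2 1.21, camera adjusted p = 5.86e-12; adjusted p = 0.171 with an estimated correlation), among them rplL (531 ± 10.5 to 1673 ± 65.2 CPM) and rplB (1782 ± 13.9 to 4783 ± 297 CPM). Of 23 aminoacyl-tRNA synthetases, which charge tRNAs, 21 rose and 1 fell (adjusted p = 1.4e-05; adjusted p = 0.213 with an estimated correlation), with ileS at 1.07 and glyQS at 1.31. The ribosomal RNA list had 18 of 22 higher and 1 lower (adjusted p = 0.0384; adjusted p = 0.521 with an estimated correlation). This call was lost without wild type library 1 (adjusted p = 0.0562), wild type library 2 (0.053) or H_D1 library 3 (0.0544). The list also holds genes of enzymes that modify ribosomal RNA. Only these were left without ribosomal RNA genes and the 10 highest genes (adjusted p = 0.761), so that setting cannot test the ribosomal RNA genes. The 5S ribosomal RNA copies in this list carry identical counts, so they are not separate measurements. Ribosomal RNA took 6.66% ± 1.27 of the H_D1 counts against 3.15% ± 1.16 in the wild type. Its share varied between libraries of a strain, from 5.25% to 7.71% in H_D1 and from 2.25% to 4.46% in the wild type. Whether this share, in any of the strains, follows the ribosomal RNA level of the cells or the making of the libraries was not tested. All 8 ATP synthase genes rose (median 1.54, adjusted p = 0.000267; adjusted p = 0.171 with an estimated correlation), led by atpF at 1.85 and atpH_2 at 1.57. Cytochrome oxidase genes had 11 of 15 higher and 4 lower, with a median of 1.25 and a mean of -1.56, as 4 members had 0 counts (adjusted p = 0.0129; adjusted p = 0.363 with an estimated correlation). NADH dehydrogenase complex I, by contrast, had 4 of 15 subunits higher and 8 lower (median -0.23) and did not pass the set test (adjusted p = 0.913). With library size alone 2 subunits were higher and 11 lower, with a median of -0.875. The tricarboxylic acid cycle list had 14 of 23 higher and 4 lower (median 0.86, adjusted p = 0.00725; adjusted p = 0.332 with an estimated correlation). Of 12 phosphate starvation genes, 10 rose and 1 fell (median 1.19, adjusted p = 0.00725; adjusted p = 0.129 with an estimated correlation). With library size alone the medians of the 7 called lists were smaller: 0.56 for ribosomal proteins (42 higher, 4 lower), 0.26 for synthetases (15, 6), 1.02 for ribosomal RNA (15, 5), 0.90 for ATP synthase (7, 0), 0.61 for cytochrome oxidases (10, 4), 0.22 for the tricarboxylic acid cycle (11, 8) and 0.55 for phosphate starvation (7, 2).

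Further lists also passed the set test in H_D1. Glycolysis and gluconeogenesis had 23 of 32 members higher and 6 lower (median 0.54, mean -1.05, adjusted p = 0.00663; adjusted p = 0.213 with an estimated correlation), and turned lower under the fry test (adjusted p = 0.00139). Aromatic amino acid and histidine synthesis had 22 of 31 higher and 3 lower (median 0.58, adjusted p = 0.000639; adjusted p = 0.0978 with an estimated correlation), with aroB_2 at 1.78 and aroH_2 at 1.30. Fatty acid degradation had 30 of 51 higher and 11 lower (median 0.54, adjusted p = 0.0049; adjusted p = 0.0978 with an estimated correlation), with fadR, a regulator inside the raised block, at 5.84 and the thiolase paaJ_1 at 3.84. With scaling by library size alone the medians of these 3 lists turned to -0.10, -0.06 and -0.10, with 13, 9 and 18 members higher and 14, 9 and 19 lower, so that their direction holds only relative to the median gene. On the lower side, 26 of 44 genes of aerial development and sporulation fell and 8 rose (median -0.59, adjusted p = 0.0444; adjusted p = 0.218 with an estimated correlation). This call was lost without wild type library 1 (adjusted p = 0.0565) or 2 (0.0566), without H_D1 library 1 (0.0636) or 3 (0.0544), with DESeq2 size factors (0.0521) and with library size alone (0.171; median -1.24). Transposases, integrases and phage genes had 16 of 29 lower and 3 higher (adjusted p = 0.0384; adjusted p = 0.258 with an estimated correlation), a call that was lost without the genes in runs (adjusted p = 0.104) and with library size alone (adjusted p = 0.132; 24 lower and 1 higher). The hypoxia and nitrate respiration list had 24 of 36 lower and 7 higher, with a median of -10.83, or -7.12 with absent genes at their bound (adjusted p = 0.000225; adjusted p = 0.101 with an estimated correlation). Of its matched genes 19 lay in the H_D1 runs, and without genes in runs the test turned upward with adjusted p = 0.734. For each of these 13 lists the counts adjusted over the list alone were the same.

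H_D34 had reads at the left end but not at the outermost right end, and expressed a wide part of both ends at a small share of the wild type level. Between ctg_07194 and ctg_07624, 370 of 379 loci expressed in the wild type had 3 or fewer counts in every library, including gap2_3 (at least 37800-fold lower), ppiA (at least 13000-fold), htpG_2, a chaperone (at least 5560-fold), the monooxygenase tet(X)_4 (at least 3680-fold), and IMPDH_4 (at least 3430-fold). The phenylacetyl-CoA epoxidase gene paaB, at ctg_07189 just outside this stretch, also had 0 counts (at least 2360-fold lower). From ctg_00002 to ctg_00286 on the left, 216 of 220 tested genes fell and 3 rose, with a median of -3.58, or 8.37% of the wild type level. From ctg_06960 to ctg_07193 on the right, 213 of 220 fell and 0 rose, with a median of -3.20, or 10.9%. The median levels in the single libraries were 8.24%, 8.53% and 8.93% on the left and 10.5%, 10.4% and 10.3% on the right. For example, the nitrate reductase beta chain gene narY_1 in the left arm went from 925.3 ± 12 to 41.5 ± 2.93 CPM.

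DNA repair polymerases were among the most raised genes of H_D34. The error-prone polymerase dnaE2 went from 10.8 ± 1.27 to 235.8 ± 21.5 CPM (log2 4.46, SE 0.08, adjusted p = 2.83e-20), its neighbour dinB, DNA polymerase IV, rose by 4.02, and uvrA_4, a nucleotide excision repair protein, by 4.04 (SE 0.06). The other genes named by the rule were femX_1, annotated as a peptidoglycan glycyltransferase (5.75), the enoyl reductase ctg_06602 (156.1 ± 4.16 to 2840 ± 132 CPM) and vgb_3 (4.04). As a list, DNA repair and SOS genes had 27 of 57 members higher, 18 lower and 12 not called, and did not pass the set test (adjusted p = 0.101). Outside the runs the lowest genes were sigE_2 (-6.96), the nitrite reductases nasD_1 (-6.50) and nasD_2 (-6.28; 489.6 ± 3.25 to 6.32 ± 0.657 CPM), sirB (-5.92), the nitrate reductase napA_1 (-5.46) and the P-II protein glnB_2 (-5.09). The nitrogen assimilation list, which holds some of these, had 14 of 25 lower and 8 higher (9 adjusted over the list alone) and did not pass the set test (adjusted p = 0.232), but passed without the genes in runs (adjusted p = 0.0236). Its members lay outside the runs, so the change was in the other genes that the list was compared with.

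In H_D34, 2609 genes were higher and 2961 lower than in the wild type, 78.6% of those tested, and 1157 and 1398 differed by 2-fold or more. Outside the runs of any mutant 2562 were higher and 2193 lower. Of 62 peptidoglycan and cell division genes, 45 fell and 7 rose (median -0.67, adjusted p = 0.000486; adjusted p = 0.211 with an estimated correlation). The penicillin-binding protein gene pbpA_1 went from 1751 ± 8.08 to 322.1 ± 4.86 CPM, and the cell wall polymer transferase gene tagU_8 fell by 2.20. NADH dehydrogenase complex I, the entry of electrons into respiration, had 13 of 15 subunits higher and 1 lower (median 0.47, adjusted p = 0.025; adjusted p = 0.325 with an estimated correlation), with nuoL_2 at 1.46 and nuoJ at 1.22. The hypoxia and nitrate respiration list had 24 of 36 lower and 10 higher (median -2.23, adjusted p = 0.00657, or adjusted p = 0.211 with an estimated correlation). The set test turned upward without the genes in runs of any mutant (adjusted p = 0.772). The list members left out there lay in runs of H_D1 or A_D28, not of H_D34. Counts adjusted over the list alone were the same for these 3 lists. All 8 chaplin and rodlin genes fell, with a median of -2.20, although the set test was not passed (adjusted p = 0.0698; 0.0236 without the genes in runs). Ribosomal protein genes had 5 higher and 30 lower of 51 (median -0.18, adjusted p = 0.232; 0.00998 without the genes in runs), but 14 higher and 14 lower with library size alone (median -0.02). No ribosomal protein gene lay in a run, so the smaller adjusted p came with the change in the other genes. ATP synthase genes had 0 higher and 5 lower of 8 (median -0.33, adjusted p = 0.368), or 1 and 3 with library size alone. Ribosomal RNA took 1.23% ± 0.595 of these libraries.

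A_D28 shared the form of H_D34, with no reads at the right end and lowered expression inward of it and at the left end. From ctg_07055 to ctg_07624, 503 of 511 expressed loci had 3 or fewer counts in every library, among them gap2_3 (at least 32700-fold lower), ppiA (at least 11300-fold), the phenylacetyl-CoA epoxidase genes paaA (at least 8830-fold) and paaC (at least 4990-fold), the flavohemoprotein hmp_5 (at least 6220-fold) and htpG_2 (at least 4810-fold). On the left, from ctg_00002 to ctg_00347, 265 of 280 tested genes fell and 6 rose (median -2.71, or 15.3% of the wild type level). On the right, from ctg_06807 to ctg_07054, 199 of 220 fell and 2 rose (median -2.76, or 14.7%). The median levels in the single libraries were 16.1%, 15.2% and 14.4% on the left and 12.6%, 13% and 14% on the right.

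DNA repair genes rose as a group in A_D28. Of the 57 listed, 42 were higher and 12 lower (13 adjusted over the list alone), with a median of 0.64, and this call held under both preset and estimated correlation (adjusted p = 0.000456; adjusted p = 0.0446 with an estimated correlation). dnaE2 went from 10.8 ± 1.27 to 315 ± 8.68 CPM (log2 4.88, SE 0.08) and dinB from 4.76 ± 0.494 to 130.0 ± 6.57 CPM (log2 4.76, SE 0.10). The most raised annotated gene was femX_1 (4.23 ± 1.09 to 399.3 ± 3.71 CPM, log2 6.58, adjusted p = 2.95e-22). Its neighbours cdhR_2, a transcriptional regulator (4.45), and smc_1, annotated as a chromosome partition protein (3.63), rose with it, as did ctg_06602 (3.97) elsewhere in the locus order. Outside the runs, sigE_2 fell to 3.16 ± 0.388 CPM (log2 -7.52), followed by nasD_1 (-6.12), nasD_2 (-6.11), sirB (-5.90), napA_1 (-5.19) and the ammonium channel gene amt (574.8 ± 5.33 to 18.3 ± 1.52 CPM, log2 -4.96). The nitrogen assimilation list had 15 of 25 lower and 10 higher and did not pass the set test (adjusted p = 0.543).

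In all, 2567 genes were higher and 3059 lower in A_D28, 1154 and 1587 of them by 2-fold or more; the higher share was 45.6%, or 35.2% on the log2(TPM + 1) scale. Complex I had 13 of 15 subunits higher and 1 lower (median 0.78, adjusted p = 0.00171; adjusted p = 0.241 with an estimated correlation), with nuoL_2 going from 71 ± 2.68 to 356.4 ± 14.7 CPM and nuoJ rising by 1.96. All 8 ATP synthase genes fell (median -0.85, adjusted p = 0.0258; adjusted p = 0.409 with an estimated correlation), including atpA (-0.97) and atpD (-0.89). Of 51 ribosomal protein genes, 35 fell and 3 rose (median -0.32, adjusted p = 0.0313; adjusted p = 0.671 with an estimated correlation). Ribosomal RNA took 4.32% ± 0.589 of these libraries and the transfer-messenger RNA gene ssrA 11.96% ± 0.516, against 7.57% ± 0.109 in the wild type. Peptidoglycan and cell division had 43 of 62 lower and 13 higher (median -0.57, adjusted p = 0.0206; adjusted p = 0.369 with an estimated correlation), with pbpA_1 at -2.01 and the sporulation division gene ssgB_4 at -2.62. Fatty acid degradation had 31 of 51 higher and 16 lower (median 0.56, adjusted p = 0.0258; adjusted p = 0.229 with an estimated correlation), with aidB_1 at 3.33 and lcfB_5 at 2.27. Potassium and osmotic stress genes had 21 of 36 higher and 7 lower (median 0.44, adjusted p = 0.049; adjusted p = 0.241 with an estimated correlation). Without genes in runs these last lists missed the threshold (adjusted p = 0.0665 and 0.108). The potassium list also missed it with the replicate number as a block (adjusted p = 0.0532), without wild type library 2 (0.0535), with DESeq2 size factors (0.0563) and with library size alone (0.0552). The hypoxia list had 24 of 36 lower and 7 higher (median -1.51, adjusted p = 0.00509, or adjusted p = 0.241 with an estimated correlation). Its set test turned upward without the genes in runs of any mutant (adjusted p = 0.917). Of its matched genes 2 lay in the A_D28 runs and 19 in the H_D1 runs. Adjusted over the list alone, the counts of these 7 lists were the same. On the log2(TPM + 1) scale the medians were 0.511 for complex I, -0.568 for ribosomal proteins, 0.305 for fatty acid degradation and 0.172 for the potassium list. With library size alone 20 genes of the potassium list were higher and 12 lower.

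**Figure D3:**
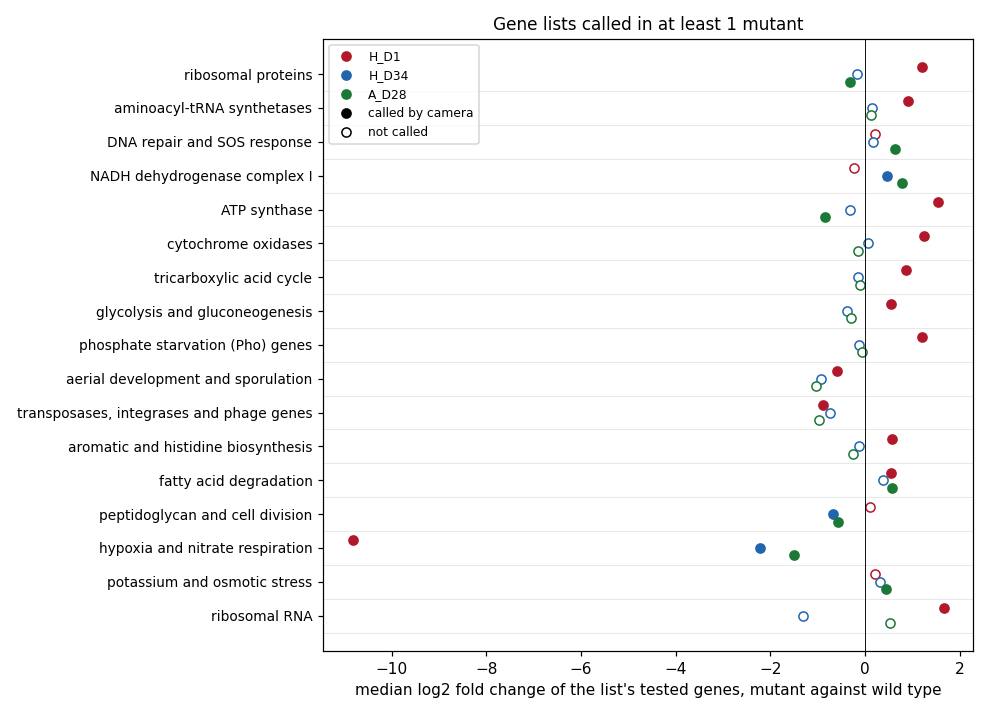
Median log2 fold change (horizontal axis) of each gene list called in at least 1 mutant, against the wild type in H_D1, H_D34 and A_D28; filled points passed the camera test and open points did not. Ribosomal protein genes have medians of 1.21, -0.18 and -0.32, and ATP synthase genes 1.54, -0.33 and -0.85.

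The genes that changed most in all 3 mutants included DNA polymerases of damage tolerance on the higher side. On the lower side, outside the runs, they included regulators of nitrogen metabolism and envelope stress. As lists, DNA repair passed the set test in A_D28 but not in H_D1 (adjusted p = 0.0854) or H_D34 (0.101), and nitrogen assimilation passed in none of the 3 (0.145, 0.232 and 0.543) with all tested genes. Without the genes in runs nitrogen assimilation was lower in H_D1 (0.00682) and H_D34 (0.0236) but not called in A_D28 (0.166). Its members lay outside the runs, so these values moved with the other genes. The annotated genes that rose most in the least affected mutant were dinB (log2 3.60 in H_D1, 4.02 in H_D34 and 4.76 in A_D28), femX_1 (3.14, 5.75 and 6.58), dnaE2 (2.80, 4.46 and 4.88), cdhR_2 (2.62, 3.61 and 4.45), the efflux gene qacA_4 (2.46, 2.43 and 3.16) and aidB_1 (2.60, 2.42 and 3.33). Outside the runs the shared low genes were sigE_2, cseA (-3.92, -4.36 and -4.29), a lipoprotein gene next to it, ctg_01608, chpE (-4.10, -4.47 and -4.35), glnB_2 (-3.94, -5.09 and -4.94) and glnD (-3.78, -4.61 and -4.62), which encodes the enzyme that modifies P-II proteins. The recombinase gene recA rose from 260.2 ± 10.1 CPM to 872.4 ± 86.2 in H_D1, 660.9 ± 22.2 in H_D34 and 1193 ± 19.8 in A_D28, while lexA, the repressor of the SOS response, fell slightly (-0.44, -0.41 and -0.16). Both directions held with each scaling of the counts for recA and lexA, whereas the small rises of dinB1 (0.52), ku_1 (0.57) and uvrB (0.52) in H_D1 turned to -0.12, -0.07 and -0.13 with library size alone. These SOS genes beyond dinB and dnaE2 were chosen after their values were seen.

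**Figure D4:**
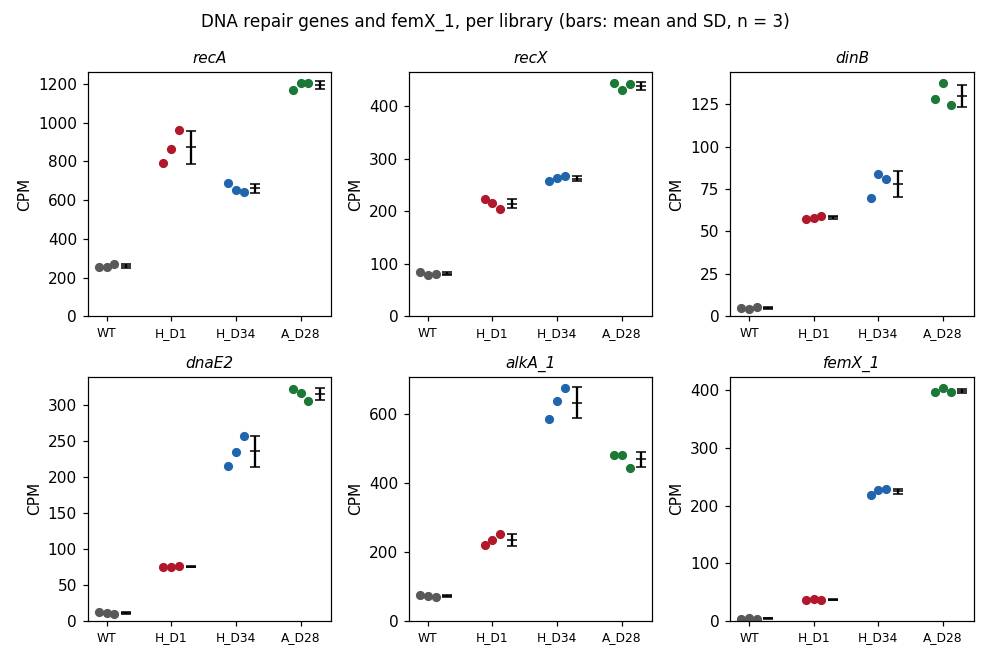
CPM (linear axis from 0) of recA, recX, dinB, dnaE2, alkA_1 and femX_1 in each of the 12 libraries, with the mean and SD of each strain (n = 3). The mean of recA is 260.2 CPM in the wild type and 660.9 to 1193 in the mutants, and the mean of dnaE2 is 10.8 CPM in the wild type and 74.9 to 315 in the mutants.

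Altogether 6618 genes differed among the 4 strains, 1136 were higher in all 3 mutants and 1728 lower in all 3. The shared higher genes numbered 495 with library size alone and 406 and 410 on the log2(TPM + 1) and log2(TPM + 0.1) scales, and the shared lower genes 1053 when the genes in runs were left out. Of the shared lower genes 766 lay in a run of at least 1 mutant and 962 outside, and 389 loci lay in the runs of all 3 mutants. Independent lists of the same sizes would share 340.8 and 500.7 genes. Because the comparisons share the wild type libraries, unchanged groups were simulated: no more than 1 gene was called in the same direction in any pair of mutants. Draws without a change hold few calls, so this count does not measure how much of the overlap comes from the shared libraries. Outside the runs the correlation of log2 fold changes across genes was 0.47 between H_D1 and H_D34, 0.426 between H_D1 and A_D28 and 0.876 between H_D34 and A_D28, with simulated means of 0.411, 0.402 and 0.465. The covariance was 0.653, 0.603 and 1.18, against simulated values of 0.0114, 0.0114 and 0.0117, so that library-to-library spread of the shared controls accounts for little of it. A deviation common to all 3 wild type libraries would also be shared, and was not simulated. The 3 wild type libraries were too few to split.

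H_D34 and H_D1 differed most at the raised block and at the ends. rutD_5 (log2 -8.92), ywiE (-7.06), ctg_06808 (-7.01) and yajO_9 (-6.92) of the block were lower in H_D34. Genes without reads in H_D1 were seen in H_D34: ppdK_1 (at least 1060-fold higher), narG_1 (at least 946-fold) and ctg_00116 (at least 916-fold) of the left end and dhmA_2 (at least 1310-fold) of the right. Outside the runs xylE_2, a xylose symporter (3.86, SE 0.56), and fabH_4 (3.69), bioF (3.59) and auaH_2 (3.56) were higher in H_D34. Ribosomal protein genes were lower in H_D34 than in H_D1, with 49 of 51 lower and 1 higher (median -1.41, adjusted p = 1.22e-13; adjusted p = 0.147 with an estimated correlation). All 8 ATP synthase genes were lower too (median -1.85, adjusted p = 0.000176; adjusted p = 0.147 with an estimated correlation). The ribosomal RNA list had 18 of 22 lower and 3 higher (median -3.17, adjusted p = 0.0189, or adjusted p = 0.545 with an estimated correlation). Its enzyme genes, left without ribosomal RNA genes and the 10 highest genes, turned upward without a call (adjusted p = 0.313). Complex I had 12 of 15 higher and 1 lower (median 0.70, adjusted p = 0.0302; adjusted p = 0.349 with an estimated correlation). With TMM factors 5206 genes differed, 55.5% of them higher in H_D34, and with library size alone 5802 differed, 83.7% of them higher, a scaling that shifted the median gene by 0.80. With it the peptidoglycan list, 42 of 62 lower (median -0.75, adjusted p = 0.000176; adjusted p = 0.147 with an estimated correlation), turned to a median of 0.05, with 26 higher and 23 lower. The other medians became -0.60 for ribosomal proteins, -1.05 for ATP synthase, -2.36 for ribosomal RNA and 1.5 for complex I.

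A_D28 and H_D1 differed in the same places. rutD_5 (-11.29), yajO_9 (-11.05) and ywiE (-10.81) were lower in A_D28, and ctg_06808 had 2 counts against 3429, a ratio of 2690 (95% counting interval 743 to 22200). ppdK_1 (at least 3020-fold higher), narG_1 (at least 2620-fold), ctg_00116 (at least 2110-fold) and ctg_00143 (at least 1520-fold) of the left end had 0 counts in H_D1 and reads in A_D28. Outside the runs lapB (4.48), ahpD_1, an alkyl hydroperoxide reductase (3.63), pepE_3 (3.61) and hpd, of tyrosine degradation (3.58), were higher. Ribosomal protein genes had 48 of 51 lower and 0 higher in A_D28 (median -1.54, adjusted p = 5.19e-14; adjusted p = 0.167 with an estimated correlation), and ATP synthase genes all 8 lower (median -2.40, adjusted p = 7.91e-05; adjusted p = 0.167 with an estimated correlation). Complex I had 14 of 15 higher (median 0.99, adjusted p = 0.00251; adjusted p = 0.21 with an estimated correlation). DNA repair had 38 of 57 higher and 10 lower (median 0.39, adjusted p = 0.00858; adjusted p = 0.167 with an estimated correlation). With TMM factors 5086 genes differed, 54.4% of them higher in A_D28, and with library size alone 5337 differed, 74.4% of them higher, a shift of 0.52 in the median gene. The list medians then became -1.02 for ribosomal proteins, -1.88 for ATP synthase, 1.51 for complex I and 0.92 for DNA repair.

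A_D28 and H_D34 were the closest pair, with 3631 genes different and 599 of these by 2-fold or more. Genes between their right-hand edges had 0 counts in A_D28 and some in H_D34: ctg_07074 (at least 333-fold lower), hmp_5 (at least 283-fold), ligD_4, of DNA end joining (at least 199-fold), and czcO_2 (at least 163-fold). Outside the runs ywiE (-3.75), ndh (-3.29), and ramC (-3.69) and ramA_3 (-3.29), which belong to the SapB lantibiotic-like peptide of aerial growth, were lower in A_D28. The NADH dehydrogenase-like gene yjlD_1 was higher (3.69, adjusted p = 9.6e-12), as were the 5S ribosomal RNA copies ctg_01359, ctg_01772 and ctg_03018 (2.70, SE 0.72, adjusted p = 0.00375), which carry identical counts and were not called by DESeq2 (adjusted p = 0.147). DNA repair had 34 of 57 higher and 7 lower (36 and 7 adjusted over the list alone; median 0.32, adjusted p = 0.000383; adjusted p = 0.0539 with an estimated correlation). Complex I had 10 of 15 higher (11 adjusted over the list alone; median 0.34, adjusted p = 0.00198; adjusted p = 0.333 with an estimated correlation). On the log2(TPM + 1) scale the medians of these 2 lists were -0.003 and -0.04, and with library size alone 22 and 5 members were higher and 18 and 1 lower. All 8 ATP synthase genes were lower (median -0.58, adjusted p = 0.000383; adjusted p = 0.311 with an estimated correlation). So were 24 of 51 ribosomal protein genes, with 5 higher (median -0.15, adjusted p = 0.0296; adjusted p = 0.608 with an estimated correlation), a call that was lost without H_D34 library 1 (adjusted p = 0.138). With library size alone 42 of them were lower and 2 higher (median -0.43). Of 16 arginine synthesis genes 10 were higher and 0 lower (median 0.41, adjusted p = 0.00633; adjusted p = 0.38 with an estimated correlation), or 7 higher and 3 lower with library size alone (median 0.14). Of the 22 members of the ribosomal RNA list 16 were higher and 2 lower (median 1.75, adjusted p = 0.00633, or adjusted p = 0.572 with an estimated correlation). Its enzyme genes, left without ribosomal RNA genes and the 10 highest genes, turned downward without a call (adjusted p = 0.563). The higher share of the genes called was 49.2%, or 18.9% of the genes called with library size alone, which shifted the median gene by -0.28.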

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

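The tests of the absent ends, of the raised block and of scaling for the ribosomal proteins were chosen only after those results were seen, whereas the matched lists for the ribosomal proteins and the splits of the libraries were not. The results listed first were singled out because the mutants differed from each other under the same comparison with the wild type. Ribosomal protein genes were higher in H_D1 and lower in A_D28, and the difference between these mutants passed camera with adjusted p = 5.19e-14 (0 of 51 higher and 48 lower, median log2 -1.54; 9.34e-21 to 0.167 over the other camera settings). ATP synthase genes did the same, with adjusted p = 7.91e-05 for the difference (8 of 8 lower in A_D28, median -2.40; 2.35e-07 to 0.167 over the other camera settings). Both calls were lost with an estimated correlation (adjusted p = 0.167 each) and in no other camera setting. Genes called in opposite directions against the wild type, with a called difference between the mutants, numbered 1223 for H_D1 and H_D34, 1288 for H_D1 and A_D28, and 243 for H_D34 and A_D28. Each strain had 3 libraries, too few for a test of single libraries that stand apart.

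The ends without reads in the 3 mutants were set against depth and against silencing. Lower depth is excluded: at the mutants' depth the wild type levels would have given a median of 212 counts per absent locus in H_D1, 307 in H_D34 and 304 in A_D28. The counts seen over these loci were 7 of 1122330 expected, 14 of 668183 and 26 of 804617, at most 0.00323%. These loci had been chosen for 3 or fewer counts in every library, so a small share was built in. All loci of the terminal segments together had 1079 (left) and 412 (right) counts in H_D1, 487 in H_D34 and 381 in A_D28. Loss of the ends from the chromosome may account for the missing reads. Loci that are present and fully silent would give the same counts, and no DNA data were used here. Both readings stay open, as does the strain difference itself, whose cause was not tested.

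The raised block of H_D1 next to its right-hand segment without reads was set against scaling and against extra copies. Scaling is excluded, since the median log2 fold change of the block was still 5.19 with library size alone. If every locus had gained the same number of copies, the fold changes within the block might be as even as among neighbours elsewhere. Their interquartile range was 1.48, above the median of 1.03 but within the range of 0.507 to 2.66 over 141 stretches of as many genes, of which 16 were wider. Unlike the block, those stretches were not bounded by their fold changes, so the ranges are not strictly alike. Amplification and raised transcription of the block therefore cannot be told apart, because copy number was not measured.

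The higher ribosomal protein genes of H_D1 were set against scaling and against gene length and level. With library size alone 42 of 51 were still called higher, with a list median of 0.56 where the median of all genes was -0.68, so scaling alone is excluded. Lists matched on length and expression level had a median fold change of 0.67, the highest of 10000 reached 0.97, and the list itself had 1.21 (one-sided share 1e-04, the smallest that 10000 lists can give). Lists of the same length and level thus rose less than the ribosomal protein genes, although length and level may carry part of the rise. The random lists drew genes singly, so the share does not allow for ribosomal protein genes that vary together. A difference in growth between cultures of the strains stays open and was not tested.

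The strain labels were also permuted. In 100 regroupings of the 12 libraries, the real one included, no other gave as many genes that differed among strains (6618, highest other 3260), that were higher in all 3 mutants (1136, highest other 880) or lower in all 3 (1728, highest other 1108), 1 of 100 each. Random assignment of these libraries to strains is therefore an unlikely source of these counts. Chance differences between single cultures are not excluded, since the 3 libraries of a strain could be technical. For each comparison of 3 with 3 libraries there are only 10 splits, too few for a share under 0.05. The real counts there were 2557 and 2778 for H_D1, 2609 and 2961 for H_D34, 2567 and 3059 for A_D28, and 5206, 5086 and 3631 for the pairs of mutants, and the highest other split gave 0 each time (1 of 10 splits as large). The lists called were 13 in H_D1 (highest other 11), 3 in H_D34 (highest other 6; 8 of 10 splits had as many), 8 in A_D28 (highest other 7), and 15, 13 and 9 for the pairs H_D34 and H_D1, A_D28 and H_D1, and A_D28 and H_D34 (highest other 11, 9 and 6). Except in H_D34, the real split was the 1 of 10 with as many lists.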

How the results depend on the processing

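The set tests with other scalings, without ribosomal RNA and the 10 highest genes or without genes in runs, the oxidative stress list without the deoxyribo- matches and the shared lower genes outside runs were chosen only after the data were seen. Over the 13 other settings for gene counts (12 for any strain), the calls ranged from 1007 to 2553 higher and 2064 to 4595 lower in H_D1, from 2186 to 3053 and 2350 to 3236 in H_D34, and from 1909 to 2640 and 2381 to 3558 in A_D28. For the pairs they ranged from 4433 to 5802 (H_D34 and H_D1), 4399 to 5502 (A_D28 and H_D1) and 3257 to 4249 (A_D28 and H_D34), and from 5319 to 6857 for any strain. H_D1 moved most: with library size alone 1115 genes were higher and 4575 lower, with log2(TPM + 1) 1011 and 4595, and with log2(TPM + 0.1) 1007 and 4590. The genes higher in all 3 mutants then numbered 495, 406 and 410. These settings omit the TMM factor, which is 0.712 in H_D1. Without the genes in runs 1053 genes were lower in all 3 mutants. Of the 1728 with all genes, 766 lay in runs and 962 outside. The refit also shifted fold changes by a median of -0.067 in H_D1, -0.068 in H_D34 and -0.066 in A_D28. With these genes left out, camera called 9 lists in H_D34 against 3. Nitrogen assimilation and ribosomal proteins had no members in runs. Their calls there came with a change in the other genes, against which camera compares a list. For the other lists the cause was not tested. Named genes gave the same direction and call in 3473 repeats; in 4, all of the 5S ribosomal RNA copies, the DESeq2 test made no call, and none reversed.

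The number of lists called depended on the correlation between genes and on the kind of set test. With an estimated correlation, the lists called fell to 0 in H_D1, 0 in H_D34 and 1 in A_D28, and to 0, 0 and 0 for the pairs H_D34 and H_D1, A_D28 and H_D1, and A_D28 and H_D34. fry, which asks whether members changed at all rather than more than other genes, called 31, 31, 33, 35, 33 and 28 lists in the same order, and in its mixed form 36, 36, 36, 36, 36 and 35. Over all lists and settings, 871 repeats kept direction and call, 100 lost the call and 8 reversed. Glycolysis in H_D1 turned lower under fry (adjusted p = 0.00139), with a mean of -1.05 and 4 members at 0 counts. Without ribosomal RNA and the 10 highest genes, the members left, which encode enzymes that modify ribosomal RNA, reversed (adjusted p = 0.313 for H_D34 and H_D1, 0.563 for A_D28 and H_D34). Without the genes in runs of any mutant the hypoxia list reversed in H_D1 (0.734), H_D34 (0.772) and A_D28 (0.917). It also reversed for H_D34 and H_D1 (0.377) and for A_D28 and H_D1 (0.206). Of its matched genes 19 lay in the runs of H_D1 and 2 in those of A_D28. For H_D34 the list members left out were thus absent in another mutant, not in H_D34.

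Windows of 50 genes passed as higher in 12.1% of windows in H_D1, 21.6% in H_D34 and 16.7% in A_D28, against 24 of 312, 35 of 337 and 24 of 330 windows of 20, and the cause was not tested. Leaving out each library in turn gave 2455 to 2558 higher and 2638 to 2715 lower in H_D1, 2484 to 2536 and 2852 to 2914 in H_D34, and 2472 to 2501 and 2962 to 2998 in A_D28. The pairs gave 4961 to 5078, 4886 to 4962 and 3277 to 3392, any strain 6542 to 6628, and the shared genes 1054 to 1157 higher and 1661 to 1744 lower. The replicate numbers pair no libraries across strains: residuals of libraries with the same number correlated at -0.121 to 0.102, and 5 of 12 libraries correlated best with their own number. With the replicate number as a block, the counts were 2521 and 2750 in H_D1, 2575 and 2936 in H_D34, 2546 and 3040 in A_D28, 5128, 5016 and 3477 for the pairs, 6573 for any strain, and 1114 and 1715 for the shared genes. The lists called were 13, 3, 7, 15, 13 and 8 with this block. The counts were whole numbers, so a fit to unrounded counts was not run. Depth limits the folds of genes without reads to the bounds given, since 3 counts over a group are the floor.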

Other observations

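The regions, single genes and list described in this part, and the tests of the lowered arms and of lexA, were chosen only after those results were seen. A short stretch from ku_1 to smc_1 (ctg_00534 to ctg_00539), which holds a DNA end-joining gene, femX_1, cdhR_2 and 2 unannotated genes, was higher in all 3 mutants, except that ku_1 in H_D1 turned to -0.07 with library size alone, with medians of 2.88, 4.68 and 5.51 in H_D1, H_D34 and A_D28. Its gene ctg_00537 went from 14.3 CPM in the wild type to 3552, 3970 and 9186, and ctg_00536 from 8.47 to 446.1, 1250 and 2335. Elsewhere other repair genes rose: recX by 1.41, 1.70 and 2.44, the DNA glycosylase gene alkA_1 by 1.70, 3.14 and 2.70, and uvrA_4 by 1.80, 4.04 and 3.10, each with the same direction at library size alone. The SOS list genes ruvA and ruvC rose in A_D28 (0.41 and 0.81) and were not called in H_D1 or H_D34, and recN fell in all 3 (-0.30, -0.58 and -0.68).

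Genes of secondary metabolism were described in a region picked for its values and in a fixed list. In the region from redW to pigC, which holds genes of the red prodiginine pigment, 17 genes were tested and 16 rose and 0 fell in H_D34 (median 1.25). In H_D1 0 rose and 11 fell (median -1.56), and in A_D28 3 rose and 10 fell (median -1.21). Between mutants, 17 of 17 were higher in H_D34 than in H_D1 (median 2.73) and 16 of 17 lower in A_D28 than in H_D34 (median -2.58). The fixed polyketide and nonribosomal peptide list, in contrast, was not called in H_D1, H_D34 or A_D28 (medians -0.65, -1.26 and -1.36; camera adjusted p = 0.0965, 0.0852 and 0.076) nor between any 2 mutants (adjusted p = 0.879, 0.679 and 0.911, medians of 0). A stretch of 21 genes from caeB (ctg_04112) to ctg_04132 was lower in all 3 mutants, with medians of -2.48, -3.34 and -3.78, and 14 genes from ctg_06117 to ctg_06130 had medians of -1.63, -1.61 and -1.97. Of genes with 100 or more counts in the wild type, 1, 11 and 2 were absent outside the terminal segments in H_D1, H_D34 and A_D28. The oxidative stress list was not called in H_D1, H_D34 or A_D28 (adjusted p = 0.93, 0.794 and 0.74), nor was the list without deoxyribo- matches put in its place (adjusted p = 0.535, 0.651 and 0.446).

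A hypothesis for the lowered but present arms of H_D34 and A_D28 is that a part of the cells lacks the arm, which would lower every locus by about the same share. The interquartile range of the right arm of H_D34 was 1.99 (95% interval 1.64 to 2.38), above the highest of 27 stretches elsewhere (1.39). The 95% intervals of the arms come from resampling genes, not libraries. They treat neighbouring genes as independent, so they may be too narrow. This arm as bounded held 4 genes with 0 counts in all 3 libraries, among them paaB, so its range is not that of lowered genes alone. The other arms held 2 (H_D34 left), 3 (A_D28 left) and 2 (A_D28 right) such genes. With genes of 30 or more expected counts the interval of the right arm of H_D34, 1.51 to 2.47, reached the highest stretch elsewhere (1.51). The ranges of 1.61 for the left arm of H_D34, 1.63 for the left arm of A_D28 and 1.45 for its right arm had intervals that reach the highest stretch elsewhere over all genes (1.39, 1.49 and 1.5). For the genes that kept reads, a mixture of cells may therefore apply in each arm and cannot be told apart from lower transcription. If the same cells lacked both arms, the ends might share one median. Right minus left was -0.054 in A_D28 (95% interval -0.37 to 0.21), which goes with it. In H_D34 it was 0.38 (0.12 to 0.70), which leaves it open. In each single library of A_D28, however, the right arm was lower than the left. The levels were 12.6%, 13% and 14% of the wild type on the right against 16.1%, 15.2% and 14.4% on the left. The test therefore does not set these mutants apart.

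Another hypothesis was that the raised recA, recX, dinB and dnaE2 reflect release of the LexA-repressed genes as a group. lexA, which represses its own gene, would then be higher, but it was called lower in all 3 mutants, the highest value being -0.16 in A_D28 (adjusted p = 0.00556). So lexA itself did not rise together with recA, recX, dinB and dnaE2. Its values were known when the test was chosen, and the test rests on lexA alone. It therefore cannot decide whether the group was released, and what raised these genes stays open.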
